A study of Mus musculus with 2 samples.

How the data were processed

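Liver messenger RNA was profiled in wild-type mice and in mice lacking Adipoq, the gene for the adipocyte hormone adiponectin. Per the labels' protocols, the animals were 12-week-old males of the C57BL/6J strain, fasted overnight, and RNA from 9 to 10 animals of a genotype was combined into 1 sequencing library. The design therefore holds 2 libraries, 1 for each genotype, prepared from cDNA fragments selected by size on a gel and sequenced on an Illumina Genome Analyzer II. Each library was assigned to its genotype by the genotype label.

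The deposited values are FPKM (fragments scaled to transcript length and to the total of mapped fragments), 1 value per gene symbol and library. Per the submitters' processing notes, TopHat and Cuffdiff were used with the mouse builds mm9 and NCBIM37. The role of each program, the versions, the annotation and any filter on rows are not given in the sources used here. The lowest value of the higher library was 0.548 FPKM over all rows. The 2 tables list the same 13352 rows in the same order, which cover 13326 gene symbols. For the 26 symbols found in 2 rows, the row with the higher mean was kept. Counts of reads were not used here, and the depth behind each value is unknown. Low values were checked for steps shared by genes, which whole reads would leave. At most 5 of 1303 genes under 1 FPKM in both libraries had the same log2 ratio to 3 decimals, so no reads were recovered.

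Expression was compared as log2((knockout FPKM + 1) / (wild-type FPKM + 1)) for the 11985 genes with at least 1 FPKM in at least 1 library. This scale understates the difference of low genes. The median of this ratio over all these genes was -0.15. Ratios are given relative to the all-gene median, and the words higher and lower refer to that reference unless FPKM as deposited are named. With 1 library per genotype no test across samples was possible. No p-value is given, and no difference has a replicate check. Genes with a log2 ratio of at least 1 in either direction were counted as at least 2-fold apart, on the values as deposited. A gene listed at 0 in 1 library is described as such, with no fold.

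The median ratio of a gene list was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list with at least 5 measured members was said to stand apart at or below percentile 2.5 or at the mirror position at the upper end. These percentiles describe the pair of libraries, not the genotypes. About 1 in 20 lists would stand apart by chance if the members of a list varied independently, and more if they vary together. There were 50 lists. They covered glucose metabolism (gluconeogenesis, glycolysis and pyruvate use, glycogen metabolism, insulin signalling) and lipid metabolism (fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation and ketone synthesis, PPAR alpha targets, lipid uptake and storage, apolipoproteins, bile acid and sterol transport, ceramide enzymes). Further lists held adiponectin and its receptors, liver transcription factors, HNF4A targets, oxidative phosphorylation, the mitochondrial genome, the tricarboxylic acid cycle, the urea cycle and amino acid catabolism, xenobiotic enzymes, and NRF2 and glutathione genes. Stress and regulation were covered by endoplasmic reticulum stress, heat shock, immediate early genes, the glucocorticoid and fasting response, the circadian clock, cell cycle and ribosomal proteins. Inflammation was covered by acute phase, complement and coagulation, interferon response, antigen presentation and cytokines. Sex-biased expression and zonation were covered by major urinary proteins, male-biased and female-biased liver genes, and pericentral and periportal hepatocyte genes. Other cells were covered by Kupffer cell, lymphocyte, neutrophil, endothelium, stellate cell, cholangiocyte, adipocyte, pancreatic acinar, erythroid and skeletal muscle markers. The last lists held the genes flanking Adipoq on chromosome 16 and markers of C57BL/6 substrains.

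Genes named in the text were chosen by a rule based on size. The rule takes Adipoq first, then the 12 highest and the 12 lowest log2 ratios among genes with at least 5 FPKM in at least 1 library, passing over pseudogenes and unnamed gene models. It adds the 2 members of each list farthest from 0 on the ratio before centring on all genes, or 4 for the lists on glucose, lipid and adiponectin, the 5 most abundant genes, and hallmark genes, among them Pck1, G6pc, Cpt1a, Fasn, Srebf1, Cyp7a1, Ppara, Hnf4a, Adipor1, Adipor2, Igfbp1 and Fgf21. Genes outside this rule are marked where they appear as chosen after their values were seen. Adipoq and Fgf21 were not analysed here, and some genes that the rule takes are not reported here. The groups, the measures, the lists, the naming rule and the first set of alternative settings were fixed before the data were examined. These settings were pseudocounts of 0.1 and 0.5 FPKM, no minimum or a minimum of 5 FPKM, division by the median ratio or by the upper quartile, rescaling to equal sums, thresholds of 1.5-fold and 3-fold, summed rows, the mean in place of the median, and 10 expression bins.

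After the data were seen, the log2 ratio was compared with transcript length and GC content. Of the symbols, 12824 (96.2%) had a GENCODE M21 transcript, 1074 of them through a RefSeq synonym. The longest coding transcript was used, which can be longer than the one expressed. This annotation belongs to a later assembly than the deposited values, so it served for length and GC only and no coordinates are given. A length-corrected ratio was formed by subtracting the running median over the 501 genes nearest in transcript length. Leaving out the Mup genes, and leaving out PPAR alpha targets that the synthesis, oxidation and storage lists also hold, were further alternatives chosen at that stage.

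The counting and list steps were tested on simulated data made for the comparison of the knockout library with the wild-type library, over 11985 genes. Of 200 genes planted at 2.5-fold, 74.0% were called at least 2-fold apart. Of 200 planted at 4-fold, 100.0% were called. The ratios of all genes were capped below the 2-fold threshold before planting. The 0 false calls in either run were therefore fixed in advance and give no false-call rate. The shares called hold for ratios less spread than the real ones. Of 200 simulated lists with no shift, 2.5% stood apart, counted at both ends. Of 200 lists shifted by 0.1, 0.2 and 0.3 log2 units, 21.0%, 59.5% and 92.0% stood apart, counted at the upper end only. Ratios were shuffled among genes of like abundance, so these rates do not cover lists whose members vary together. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Reads that map to near-identical copies make values uncertain for the Mup, Saa, Scd, Ugt1a and Cyp3a families and for ribosomal proteins with processed pseudogenes. Values of very short features such as mitochondrial tRNAs, microRNAs and small nucleolar RNAs are uncertain as well.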

Results

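Liver RNA was sequenced from fasted male mice aged 12 weeks, either wild type or without Adipoq, which encodes the adipocyte hormone adiponectin. Each genotype was represented by 1 library made from the pooled RNA of 9 to 10 mice. The comparison asks how hepatic gene expression, above all that of glucose and lipid metabolism, differs when adiponectin is missing. Adipoq itself was not analysed here, so the genotype labels were not checked against the targeted gene. The wild-type library listed 11749 genes at 1 FPKM or more and the knockout library 11325, and 995 and 1032 genes reached 100 FPKM. Summed FPKM came to 798231 in the wild-type and 892016 in the knockout library. The most abundant transcripts were typical of liver. Apoa2 stood at 25947 FPKM in the wild-type and 25378 in the knockout library, Apoe at 19450.3 and 15783, albumin (Alb) at 17522 and 14031, mt-Co1 at 15535 and 16953, and mt-Co3 at 13011 and 16839. Across genes, which are not independent replicates, log2 expression in the libraries had a Pearson r of 0.986 and a Spearman rho of 0.978. The sequencing depth is unknown, and differences between the libraries have no replicate check.

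Among the genes with the lowest ratios were the stearoyl-CoA desaturases Scd1 (1912 FPKM in the wild-type and 667 in the knockout library), Scd2 (35.0 and 11.03) and Scd3 (101.0 and 29.5). The phospholipid transfer protein Pltp was lower as well (76.8 and 24.5), as were the fatty acid hydroxylase Cyp4a14 (46.5 and 15.2), the lysophosphatidylcholine transporter Mfsd2a (10.3 and 2.74), the glucuronosyltransferase Ugt1a5 (43.9 and 12.4) and the kinase Mapk15 (5.50 and 1.18). Cfd, the serine protease adipsin, showed a relative log2 ratio of -2.09, at 13.3 FPKM in the wild-type and 2.01 in the knockout library. The small transcripts mt-Tr (11.4 FPKM in wild type), mt-Tl2 (10.8) and Snord49a (5.43) were listed at 0 in the knockout library.

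At the opposite end, the acute phase genes Saa1 and Saa2 were 5.80-fold higher as deposited, at 110 and 49.3 FPKM in the wild-type and 636 and 286 in the knockout library, and Saa3 was 3.09-fold higher (10.8 and 33.3). Moxd1, a gene expressed more in male than in female liver, stood at 0.408 FPKM in wild type and 9.16 in the knockout library. The trefoil peptide Tff3 (2.52 and 20.2), the energy homeostasis peptide gene Enho (2.14 and 7.89), the interferon-inducible Ifi27l2a (11.1 and 28.3) and the endoplasmic reticulum prolyl isomerase Fkbp11 (17.1 and 39.9) were also higher. The remaining high ratios belonged to small features, namely mt-Tp (42.5 and 185), mmu-mir-2138.1 (17.0 and 43.5), mmu-mir-689-1.1 (16.4 and 40.5) and the immunoglobulin segment Igkj2, which was listed at 0 in wild type and at 8.66 FPKM in the knockout library.

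**Figure D1:**
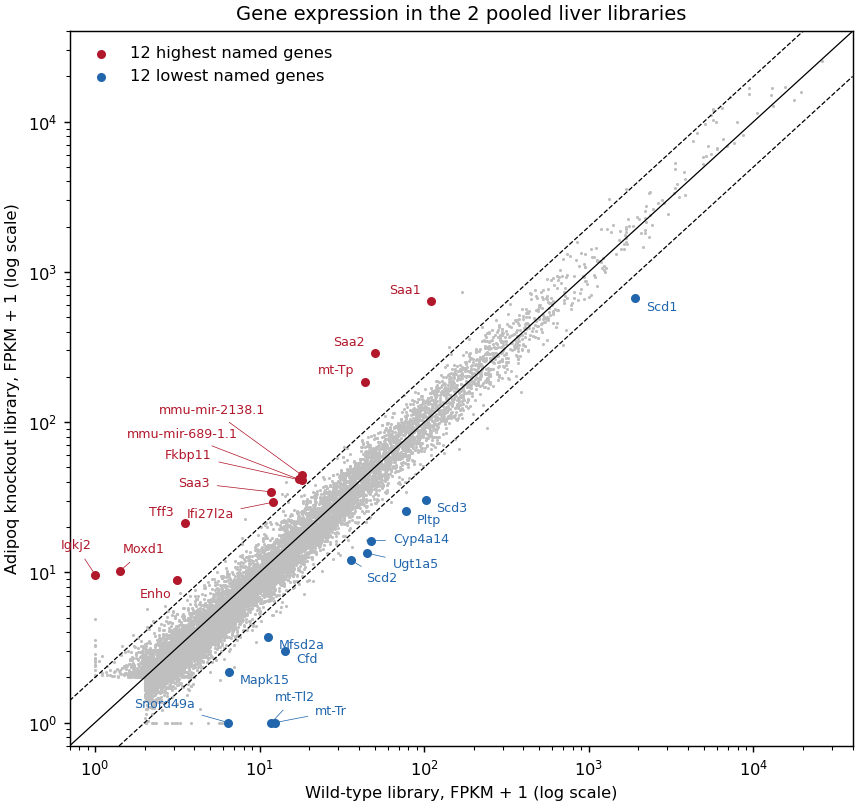
FPKM + 1 in the wild-type library (horizontal, log scale) and the knockout library (vertical, log scale) for each gene with at least 1 FPKM in at least 1 of them, with the 12 highest (red) and 12 lowest (blue) named genes; the solid line marks equal values and the dashed lines 2-fold differences. Scd1 lies below the lower dashed line at 1912 and 667 FPKM, and Saa1 above the upper one at 110 and 636 FPKM.

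On the deposited values, 55 of 11985 genes were at least 2-fold higher in the knockout library and 91 at least 2-fold lower. The higher genes included 7 with a Mup symbol, 14 small RNAs or immunoglobulin segments, and 22 pseudogenes or unnamed models. Of the lower genes, 23 were small RNAs or immunoglobulin segments and 16 pseudogenes or unnamed models. In 1 of the libraries, 16 of the higher and 24 of the lower genes were listed at 0. The split between directions depended on scaling. The higher genes made up 37.7% with FPKM as deposited, 62.9% (110 higher, 65 lower) after division by the median ratio, 20.1% (46 and 183) after rescaling to equal sums and 49.0% (76 and 79) after upper quartile scaling. Among genes with a mean of at least 10 FPKM, 95% of relative log2 ratios lay between -0.54 and 0.83.

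Of 47 gene lists with at least 5 measured members, 19 stood apart as lower and 7 as higher. About 2.4 would be reached by chance if the members of a list varied independently of each other. Members that vary together, such as close paralogs, would raise that number, so the excess over it does not exclude chance. The log2 ratio also moved with transcript length. Its median was 0.25 in the tenth of genes with the shortest transcripts and -0.27 in the tenth with the longest (Spearman rho -0.438 across 11571 genes), while GC content showed little relation (rho 0.02). After correction for length, 13 lists were lower and 10 higher, and 13 and 7 stood apart in the same direction on both scales.

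**Figure D2:**
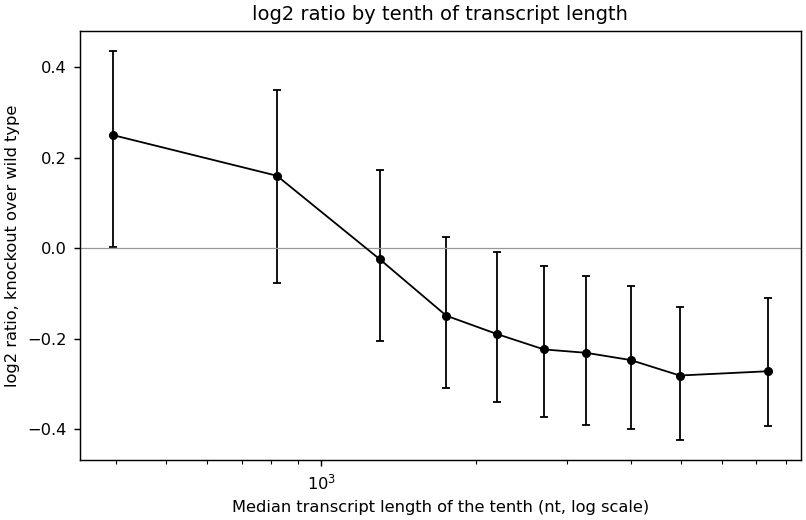
Median log2 ratio of knockout over wild-type FPKM (vertical) in 10 equal groups of genes ordered by transcript length (horizontal, median length in nt, log scale); bars give the quartiles across genes. The median is 0.25 for the shortest transcripts and -0.27 for the longest.

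Among the glucose metabolism lists, glycolysis and pyruvate use was lower, with 17 of 23 measured members below the all-gene median (list median relative log2 ratio -0.23, percentile 0.0). The pyruvate dehydrogenase kinases Pdk4 (5.04 FPKM in wild type and 1.64 in the knockout library) and Pdk1 (43.2 and 24.5) and the bifunctional enzyme Pfkfb1 (25.7 and 14.8) were among the lower members. The median of gluconeogenesis did not stand apart (-0.01, percentile 6.34), whereas its mean did (-0.06, percentile 0.42), and after length correction the median was 0.05 (percentile 53.3). Within it, Pck1, the gene for cytosolic phosphoenolpyruvate carboxykinase, was higher (145 and 196 FPKM, relative log2 ratio 0.59). G6pc, the glucose-6-phosphatase gene, was 106 and 109 FPKM (0.19). The CREB coactivator Crtc2 (10.5 and 5.55), pyruvate carboxylase Pcx (84.0 and 54.4) and Gpt2 (111 and 78.6) were lower. The medians of glycogen metabolism (-0.10, percentile 5.27) and insulin signalling (-0.08, percentile 15.6) lay within the range of random lists, but glycogen metabolism stood lower by its mean (-0.15, percentile 0.52) and with a minimum of 5 FPKM (-0.19), and not after length correction (-0.03, percentile 24.9). The glycogen branching enzyme Gbe1 was 43.5 and 26.6 FPKM, Phka2 7.51 and 4.63, Pgm2 64.9 and 45.6, and the phosphorylase Pygl 152 and 110.2. The insulin receptor gene Insr was 7.86 and 5.27, Igfbp1 7.98 and 5.94, Pdpk1 2.38 and 1.68, and Socs2 2.97 and 2.16.

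Lipid metabolism held the most extreme lower lists. For fatty acid and triglyceride synthesis, 23 of 24 measured members lay below the all-gene median and 11 were at least 1.5-fold lower relative to it (list median -0.48, percentile 0.0). Besides Scd1 (-1.37), the fatty acid elongase Elovl5 (240 FPKM in wild type and 89.9 in the knockout library), malic enzyme Me1 (76.1 and 33.1) and the acetyl-CoA synthetase Acss2 (154 and 76.6) had the lowest ratios. Fatty acid synthase (Fasn) was 145 and 106 (-0.29), whereas the lipogenic regulator Srebf1 was close to the all-gene median (218 and 194, -0.01). The targets of PPAR alpha, a nuclear receptor for fatty acids, had the lowest list median (-0.56, percentile 0.0), with 20 of 23 members below the all-gene median and 6 at least 2-fold lower as deposited. They included the lipid droplet protein gene Cidec (4.73 and 0.913), the aldehyde dehydrogenase Aldh3a2 (161 and 65.4) and the fatty acid transporter Cd36 (23.01 and 9.25). Without members held by the synthesis, oxidation and storage lists, the 17 remaining targets had a median of -0.50 (percentile 0.0). Ppara itself was 36.5 and 31.7 FPKM (-0.05).

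Fatty acid oxidation and ketone synthesis was lower by a smaller amount (-0.22, percentile 0.0, 23 of 27 members below the all-gene median). Acaa1b was 697 FPKM in wild type and 328 in the knockout library, Ehhadh 109 and 59.8, and Acaa1a 228 and 128. The mitochondrial Acadm was 110.3 and 74.8, and Cpt1a, which controls fatty acid entry into mitochondria, 40.7 and 33.4. Lipid uptake, storage and lipolysis was also lower (-0.23, percentile 0.0), with the droplet coat genes Plin2 (722 and 408) and Plin5 (11.1 and 6.204) next to Cidec and Cd36. Cholesterol synthesis stood lower (-0.17, percentile 0.01, 20 of 24 members). Its members Sc5d (358 and 200.3) and Mvd (18.2 and 11.6) were among the lowest. Bile acid and sterol transport was lower as well (-0.19, percentile 0.01, and -0.11, percentile 0.66, after length correction). The sterol hydroxylase Cyp8b1 (129 and 69.4) and the transporters Slco1a4 (15.1 and 7.74) and Abcc3 (58.5 and 34.2) were lower, Cyp7b1 was higher (74.3 and 122), and Cyp7a1, which starts classical bile acid synthesis, was 19.2 and 14.9. Apolipoproteins did not stand apart (0.04, percentile 9.38), with Apom (235 and 369) and Apoc4 (2326 and 3374) higher and Pltp and Abca1 (13.7 and 9.54) lower. Ceramide enzymes did not stand apart either (-0.12, percentile 9.92). Sgpl1 was 10.96 and 6.47 FPKM, Lass2 170.3 and 120.05, Kdsr 3.30 and 2.11, and Sphk2 15.4 and 11.1.

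**Figure D3:**
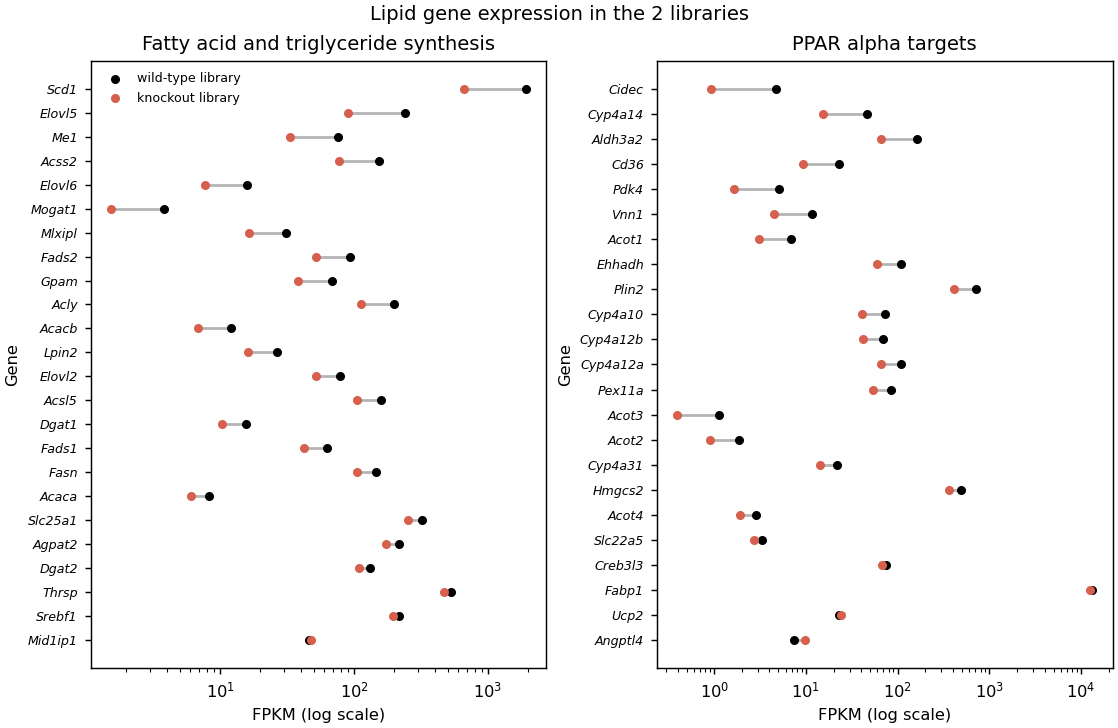
FPKM (horizontal, log scale) of the measured members of the fatty acid and triglyceride synthesis list and the PPAR alpha target list in the wild-type library (black) and the knockout library (red), 1 value per gene and library. Most knockout values lie to the left of the wild-type values, with Scd1 at 667 against 1912 FPKM and Cyp4a14 at 15.2 against 46.5 FPKM.

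The adiponectin receptors and their signalling partners stayed near other genes. The list median was -0.03 (percentile 34.1), with Adipor1 at 22.9 FPKM in wild type and 20.9 in the knockout library, Adipor2 at 154 and 116, the adaptor Appl2 at 5.62 and 3.39, and the AMP-activated kinase subunits Prkaa1 at 2.43 and 1.55 and Prkaa2 at 6.03 and 4.48. Liver transcription factors as a list were lower (-0.15, percentile 0.83), and no longer stood apart after length correction (-0.08) or with a minimum of 5 FPKM (-0.18). Pparg was 7.74 and 3.54 FPKM, the xenobiotic receptor Nr1i3 43.2 and 26.1, and Hnf4a 91.0 and 71.9. The median of HNF4A targets was 0.01 (percentile 4.32), whereas their mean was -0.05 and lay at percentile 0.05, and after length correction the median was 0.04 (percentile 39.9). Nuclear genes of oxidative phosphorylation (0.32, percentile 84.7) and the mitochondrial genome (0.31, percentile 67.1) lay within the range of lists of equal abundance, and after length correction their medians were 0.06 and 0.08. Atp5j was 606 and 904 FPKM, Ndufs1 37.8 and 26.0, and mt-Co2 7988 and 9877. The tricarboxylic acid cycle was lower (-0.13, percentile 0.1), with Dld at 70.1 and 46.9 and citrate synthase (Cs) at 41.7 and 29.2. Urea cycle and amino acid catabolism was slightly lower (-0.05, percentile 0.055), with Oat at 262 and 173 and Bhmt at 633 and 426, and was inside the random range after length correction.

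Detoxification genes were lower. The xenobiotic list had 21 of 23 members below the all-gene median (-0.22, percentile 0.0), with Aldh1a1 at 559 FPKM in wild type and 350.4 in the knockout library and the phenobarbital-inducible Cyp2b10 at 2.08 and 0.693. NRF2 and glutathione genes were lower too (-0.32, percentile 0.0, 19 of 26 members). Gclc, the catalytic subunit of glutathione synthesis, was 45.2 and 22.1, and the glutathione transferase Gsta2 33.4 and 15.4. Pericentral hepatocyte genes (-0.15, percentile 0.05) and periportal genes (-0.03, percentile 1.66) both stood apart as lower, and neither did after length correction. Agxt2l1, a periportal gene, was 38.4 and 20.5.

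Endoplasmic reticulum stress genes did not stand apart (-0.03, percentile 7.38, while their mean was 0.05). Chac1 was 1.46 FPKM in wild type and 0.450 in the knockout library, and Derl3 1.93 and 4.21. Neither did heat shock genes (0.04, percentile 39.5, with a mean of -0.0007), among which Hspd1 was 58.1 and 33.5 and Hsp90aa1 25.4 and 17.7. Immediate early and stress genes were lower (-0.29, percentile 0.01; with a minimum of 5 FPKM -0.31, which did not stand apart), with Gadd45g at 8.51 and 2.41 and Egr1 at 2.19 and 0.783. The glucocorticoid and fasting list stood apart as higher (0.23, percentile 99.2), although its members farthest from 0, Gadd45g and Pdk4, were both lower. It did not stand apart by its mean (0.10), with no minimum (0.052) or with a minimum of 5 FPKM (0.17). The circadian clock list did not stand apart (-0.01, percentile 55.2), with Arntl at 2.76 and 1.42 and Cry2 at 4.09 and 2.501. Nor did cell cycle genes (0.11, percentile 85.6, 8 measured members), with Mcm7 at 5.54 and 3.27 and Tyms at 10.7 and 7.30.

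Major urinary proteins, pheromone carriers secreted by male liver, had the highest list median (1.09, percentile 100). Each of the 10 measured members was at least 1.5-fold higher relative to all genes, and the 34 genes with a Mup symbol together made up 10.1% of summed FPKM in the wild-type and 17.0% in the knockout library. Mup20 was 7179.6 and 14550.1 FPKM, Mup12 5686 and 12223, and Mup5 140.2 and 315, although reads are hard to assign among these close paralogs. Male-biased liver genes were higher (0.47, percentile 99.97, 17 of 23 members above the all-gene median), whereas female-biased genes were lower (-0.29, percentile 0.01, 12 of 14 members below it). In the female-biased list Cyp4a14 and the peroxisomal transporter Abcd2 (4.52 and 2.08) were farthest from 0. This list shares members with other lower lists, named here after their values were seen. Cyp4a14, Cyp4a10 and Acot3 are also PPAR alpha targets, and Cyp3a41a, Cyp3a44 and Cyp2a4 are also in the xenobiotic list. The Cyp3a members Cyp3a41a, Cyp3a41b, Cyp3a16 and Cyp3a44 (-0.30, -0.30, -0.29 and -0.27) lay near the abundant paralog Cyp3a11 (-0.29). Reads are hard to assign among these copies, so they may not count as separate members. The female-biased list was not tested without the shared or Cyp3a members, so its position is not separate from those lists or from Cyp3a11. All 40 ribosomal protein transcripts lay above the all-gene median (0.59, percentile 100), with Rps6 at 125 and 206 FPKM. Length correction left 0.32 for ribosomal proteins and 0.84 for major urinary proteins, both at percentile 100.

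Acute phase genes had a median of 0.30 with 20 of 24 members above the all-gene median. This was within the range of equally abundant random lists (percentile 89.7) and stood apart by its mean (0.54, percentile 99.99) and after length correction (0.24, percentile 99.9). The mean gives weight to the paralogs Saa1 (2.68), Saa2 (2.66) and Saa3 (1.69), and was not taken without them. Interferon response genes were higher (0.22, percentile 99.95, 20 of 24 members), with Isg15 at 10.0 FPKM in wild type and 15.9 in the knockout library, but did not stand apart with a minimum of 5 FPKM (0.20). Antigen presentation was at percentile 94.0 (0.21) and stood apart by its mean (0.27, percentile 98.4) and after length correction (percentile 99.6), with the class II genes H2-Eb1 (16.8 and 31.2) and H2-Ab1 (17.6 and 31.7) farthest from 0. Complement and coagulation genes stood apart as lower among abundant genes (-0.03, percentile 0.37), with a mean of 0.02, and lay inside the random range after length correction. C1s was 135 and 90.6, and C8b 140 and 201. Cytokines did not stand apart (0.05, percentile 75.2), with Ccl5 at 2.33 and 1.30 and Myd88 at 8.27 and 5.44.

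Among the lists for other cells in the liver, Kupffer cell and stellate cell genes stood apart as higher and adipocyte genes as lower. Of the inflammatory lists, only interferon response stood apart as higher by its median. Whether these lists moved together was not tested. Kupffer cell and macrophage genes were higher (0.34, percentile 99.96, 19 of 22 members, and 0.18, percentile 99.7, after length correction), with lysozyme (Lyz2) at 72.5 FPKM in wild type and 116 in the knockout library and Marco at 1.26 and 3.73. Stellate cell and fibroblast genes were higher (0.20, percentile 98.2, and 0.32 after length correction), with Spp1 at 13.4 and 21.01, but did not stand apart with a minimum of 5 FPKM (0.13). Endothelial genes did not stand apart (0.13, percentile 96.7) but did with no minimum (0.14) and after length correction (0.21, percentile 99.8). Vwf (1.44 and 0.769) and Cdh5 (2.82 and 2.04) lay below the all-gene median, and Oit3 (9.09 and 11.6) and Esam (2.58 and 3.31), chosen after their values were seen, above it. Erythroid (0.35, percentile 94.95, and 0.08 after length correction), lymphocyte (0.09, percentile 86.1), neutrophil (0.16, percentile 89.3) and cholangiocyte genes (0.09, percentile 78.9) did not stand apart by their medians. The lymphocyte mean did (0.25, percentile 98.3), and the neutrophil median turned to -0.19 (percentile 8.95) after length correction. Their members included Car2 (1.42 and 0.964), Cd4 (1.08 and 2.36), Cd52 (8.58 and 14.3), Lcn2 (3.66 and 6.99) and Prtn3 (1.14 and 2.40). Adipocyte genes were lower (-0.40, percentile 0.02, 6 of 9 members below the all-gene median), led by Cfd and Cidec. Lists with fewer than 5 measured members were not placed among random lists. The pancreatic acinar list had 3, with Cela1 at 28.5 and 56.9 and Cela2a at 0.517 and 1.96, and the skeletal muscle list 4, with Neb at 2.04 and 0.967 and Des at 0.864 and 1.22.

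The genes flanking Adipoq on chromosome 16, where sequence from the original embryonic stem cells can remain beside a targeted allele, had a median of -0.11 (percentile 1.19) over 33 measured members. After length correction the median was -0.04 (percentile 16.1), and 4 of the other settings also ended the call. Ehhadh and Clcn2 (10.1 and 6.12 FPKM) were lower, and Ece2 (0.66) and Polr2h (0.61), chosen after their values were seen, were higher. The markers of C57BL/6 substrains had 3 measured members, among them Wdfy1 at 4.02 FPKM in wild type and 1.77 in the knockout library and Nnt at 7.999 and 5.88.

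**Figure D4:**
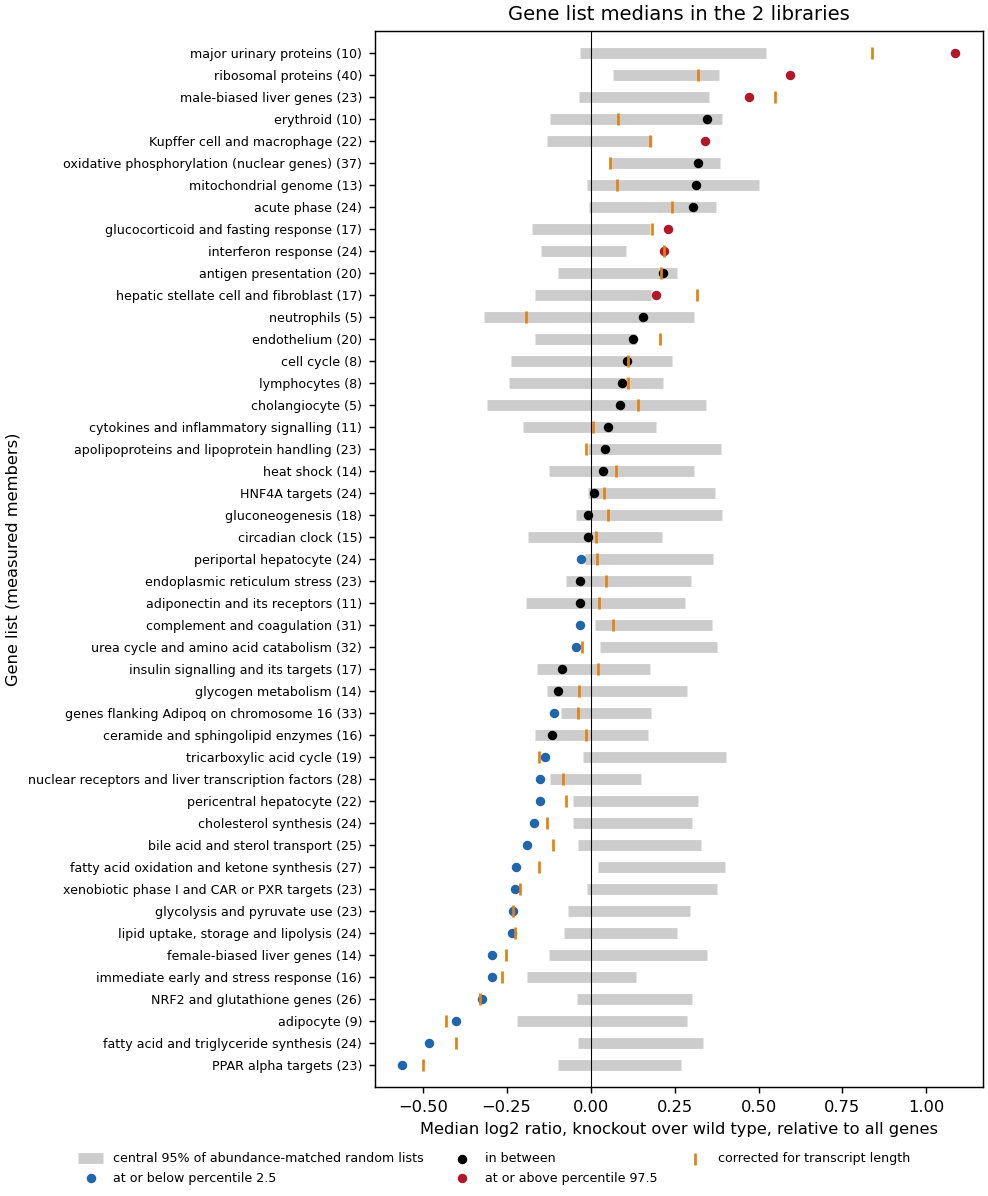
Median log2 ratio of knockout over wild type for each gene list, relative to all genes (horizontal), with the number of measured members beside each name; grey bars span the central 95% of random lists matched on abundance, and orange ticks give the median after correction for transcript length. Major urinary proteins lie highest at 1.09 and PPAR alpha targets lowest at -0.56.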

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

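Corrections for transcript length, lists without Mup genes and PPAR alpha targets without members of the synthesis, oxidation and storage lists were chosen after the data were seen; the other alternatives were planned. The number of genes at least 2-fold higher in the knockout library, 55, became 138 and 84 with pseudocounts of 0.1 and 0.5 FPKM, 29 with a minimum of 5 FPKM, 110 after division by the median ratio, 387 at 1.5-fold and 11 at 3-fold. The number lower, 91, became 303, 168 and 56 under the first 3 of these, 183 after rescaling to equal sums, 739 at 1.5-fold and 18 at 3-fold. A smaller pseudocount admits genes of low value, and a stricter minimum tests fewer genes, and the cause of the other shifts was not tested. The scaling shift, the all-gene median, moved from -0.15 to -0.0004 with median-ratio division, which centres it by construction, and to -0.29 with rescaling to equal sums. No list that stood apart did so in the opposite direction under another setting, although the relative medians of complement and periportal genes changed sign with length correction, as did that of complement genes with the mean (0.017). The number of lists standing apart as higher was 4 in place of 7 with a minimum of 5 FPKM. Of the 26 lists that stood apart, the following lost their position, and the cause was not tested. With the 5 FPKM minimum these were nuclear receptors (-0.18), immediate early genes (-0.31), the glucocorticoid and fasting list (0.17), interferon response (0.20), stellate cells (0.13) and the genes flanking Adipoq (-0.12). With length correction they were nuclear receptors (-0.081), the urea cycle (-0.025), complement (0.068), pericentral (-0.072) and periportal genes (0.020) and the flanking genes (-0.038). The flanking genes also did so with a pseudocount of 0.1 (-0.094), median-ratio division (-0.090) and the mean (-0.042), and the glucocorticoid list with no minimum (0.052) and the mean (0.10). The remaining settings left these 26 lists on their side, except that the Mup list has no value without Mup genes. Leaving out Mup genes dropped their rows without rescaling the others, and rescaling to equal sums shifts nearly all ratios alike. Neither setting could move most lists much, so their agreement says little. Of the 21 lists that had not stood apart, 6 did so with the mean (gluconeogenesis, glycogen, HNF4A targets, acute phase, antigen presentation, lymphocytes), 3 with length correction (acute phase, antigen presentation, endothelium) and 1 with no minimum (endothelium). With the minimum of 5 FPKM, 1 of the 17 with enough members did so (glycogen). Of 141 named genes, 23 and 8 moved by more than the spread of genes of like abundance with pseudocounts of 0.1 and 0.5, 0 with either rescaling, and 12 of 139 with length correction. The pseudocount alternative for Adipoq and upper quartile scaling of the lists were not run. Depth is unknown, so no limit from counting can be given, and no paired analysis was possible because each genotype has 1 library.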

Other observations

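The tests of explanations below, and the genes named here outside the naming rule, were chosen after the values had been seen. Antigen presentation genes went both ways, and no test compared the classes. Of the class II genes, H2-Aa stood at 23.5 FPKM in wild type and 41.0 in the knockout library (relative log2 ratio 0.93) and the invariant chain Cd74 at 40.5 and 55.6 (0.60). Of the class I genes, H2-K1 was 311 and 238 (-0.23), H2-D1 121 and 105 (-0.05), B2m 1640.01 and 1417 (-0.06) and H2-Q6 36.6 and 36.8 (0.16), and the peptide processing genes Tap2 (0.27) and Psmb9 (0.52) lay above the all-gene median and Tap1 (-0.14) below it. Among acute phase genes, Orm2 (247 and 397) and hemopexin Hpx (1401 and 2055) were higher, whereas the fibrinogen chain Fga was lower (1124 and 805, -0.33). Within the endoplasmic reticulum stress list, which did not stand apart, Sdf2l1 (27.0 and 43.6), Creld2 (21.02 and 30.6) and Manf (178 and 221) were higher, while Hsp90b1 (234 and 169), Pdia4 (26.5 and 19.1), Hyou1 (22.2 and 15.99), Dnajb9 (-0.24) and Dnajb11 (-0.28) were lower. Glutathione peroxidase Gpx1 (2334 and 3385) and Gstp2 (841 and 1577) were higher inside a list that was lower.

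Fatty acid synthesis genes and PPAR alpha targets were both lower in the knockout library, and their medians lay -0.48 and -0.52 from the middle of random lists matched on transcript length and abundance (percentile 0.0 for both), which argues against the length trend as the whole source. Adipose tissue in the wild-type pool is argued against for most of the summed FPKM difference. Cfd and Fabp4, abundant in adipocytes, summed to 22.9 FPKM in wild type. This was 0.685% of the 3338 FPKM by which the 44 members with lower FPKM as deposited differed, and Fabp4 was 9.61 and 10.95 FPKM. The sum is weighted toward abundant members such as Scd1 (1912 and 667 FPKM). It cannot decide for members of low FPKM or for the list medians, in which each member counts alike. The adipocyte list was itself lower, and 6 of its 9 measured members belong to another list too. For Cfd and for members of low FPKM such as Cidec (4.73 and 0.913) an adipose origin stays open. A deeper fast in the knockout pool would raise PPAR alpha targets, so by itself it does not account for their median of -0.561. That median is the pattern itself, so it cannot decide whether the pools differed in fasting. For the synthesis genes a deeper fast stays open, since the glucocorticoid and fasting list was higher (0.23) while the fatty acid oxidation list was lower. The higher position of the fasting list was lost by its mean (0.10, percentile 81.8), with no minimum and with a minimum of 5 FPKM. Loss of adiponectin may underlie the pattern, which remains a hypothesis, because a difference between the pools other than genotype was not tested.

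Major urinary proteins were higher in the knockout library. Reads moved among Mup paralogs would leave the family's total as it was, whereas FPKM times transcript length, summed over Mup genes, was 1.87-fold higher. The Mup median exceeded that of lists matched on length and abundance by 0.64 (percentile 100), which argues against the length trend as the whole source. The male-biased list was higher as well (0.47, and 0.55 after length correction), but its members Cyp4a12a (-0.56), Cyp4a12b (-0.56) and Elovl3 (-0.40) were lower. Cyp4a12a and Cyp4a12b also belong to the PPAR alpha target list, which was lower. A shift shared by male-biased genes stays open, since the values of the male-biased list are the ones that raised it. Whether genotype or another difference between the pools goes with the Mup difference stays open.

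All 40 ribosomal protein transcripts were higher in the knockout library, and short transcripts were higher in general. Random lists matched on length and abundance had a middle value of 0.34, so the trend may account for part of the list's 0.59. The remaining 0.25 lay beyond those lists (percentile 100), but the match used the longest coding transcript of each gene. Length correction lowered the relative log2 ratio of most members, but not of Rpl18 (0.60 before and 0.68 after) or Rps3 (0.82 and 0.84). The correction treated these genes as it did transcripts that are not short. The remainder may therefore be overstated. Reads moved between ribosomal protein genes and their pseudogene copies would lower the copies. The 106 pseudogene rows had a median of 0.57 (quartiles 0.47 and 0.69), and 103 of them lay above the all-gene median. These rows were not compared with other genes of like transcript length. The group of genes with the shortest transcripts, of 42 to 566 nt, had a relative median of 0.40. The pseudogene rows therefore cannot decide whether some reads moved, and that explanation stays open. The source of the length trend, for which RNA quality and fragment selection were not tested, stays open, and so does a difference between genotypes.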
